A study of Homo sapiens with 9 samples.

How the data were processed

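Gene expression was measured on 9 Affymetrix Human Genome arrays of 6 human cell lines, 2 arrays each for the B-cell lines Namalwa, SU-DHL4 and SU-DHL6 and 1 array each for the PCM lines L363, U266 and LP1. Per the labels' protocols, cells were grown in serum-supplemented RPMI medium, and total RNA was extracted with Qiagen reagents and turned into biotinylated cRNA. Per the submitters' processing notes, the Namalwa arrays were published earlier by the same group and the other 7 were newly generated. The authors normalized the arrays by RMA and deposited values in log2 units, 22283 probe sets per array. The RMA version, and whether all arrays were normalized together, are not given in the sources used here. A second deposited table held, per the file headers, a p-value and a Benjamini-Hochberg adjusted p-value for each probe set, made by the authors with a moderated t-test, and a column of differences in log2 units. Its unadjusted p-values equalled those of limma run on 9 arrays as replicates to within 5e-08, and its difference column equalled the B-cell mean minus the PCM mean, so its sign was turned for comparison. Probe-level data were not used here. Array medians lay between 6.95 and 7.04, and no detection call comes with RMA.

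The deposited values were analysed with R 4.3.3 and limma 3.58.1 without further normalization. The 68 control probe sets were left out, which left 22215. In the table of symbols used, 19065 probe sets had 1 gene symbol, 1043 had several and 2107 had none, and 11963 genes had a probe set that could be named. The comparisons, tests, gene lists, rule for naming genes and most alternative settings were fixed before the data were examined. For PCM against B-cell lines, the 2 arrays of a B-cell line were averaged, since 2 arrays of a line are not 2 lines, and lmFit and eBayes were run on 3 against 3 lines with 4 residual degrees of freedom. SU-DHL6 was compared with SU-DHL4, and Namalwa with the mean of the SU-DHL lines, on the 6 B-cell arrays with line as a factor and 3 residual degrees of freedom, where the spread is that between duplicates. Tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05. An exact permutation test of 3 against 3 lines cannot go below 0.10 and was not used for calls.

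The 30 gene lists were tested with camera at a preset correlation of 0.01 on 1 probe set per gene, the one with the highest mean over the 6 lines, with adjustment over the lists. Members were also counted at an adjusted p under 0.05 over all probe sets and adjusted over the list alone. The lists held B-cell identity, B-cell transcription factor, B-cell receptor signalling, germinal centre, MHC class II, MHC class I, plasma cell, immunoglobulin, unfolded protein response, secretory pathway, N-glycosylation, adhesion, myeloma target, IL6 and JAK-STAT, NF-kB, Hodgkin lymphoma, apoptosis, proliferation, cell cycle inhibitor, chromatin, interferon, ribosomal, oxidative phosphorylation, glycolysis, cholesterol, ATF4 target, T and NK cell, myeloid, erythroid and platelet, and epithelial, fibroblast and endothelial genes. The same list tests between B-cell lines were added after the data were examined.

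Genes were named by rule. In each direction these were the 12 genes with the largest absolute difference among called probe sets with exactly 1 symbol whose 3 PCM values all lay beyond the 3 B-cell line values, with 1 probe set per gene, and 5 per direction between B-cell lines. A set of B-cell and plasma cell genes fixed in advance was named whatever its result, at the probe set with the highest mean; 14 of its 16 genes had a probe set that could be named. Also named were up to 4 members with the smallest p in each list described. XIST and genes on the Y chromosome were not named, a restriction added after the rule was written.

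The tests were tested on simulated data with known changes. Of probe sets changed by 1, 2 and 4 (log2), the PCM comparison recovered 41.8%, 83.6% and 95.5% with 8 false calls, the SU-DHL6 against SU-DHL4 comparison 55.2%, 79.1% and 97.0% with 6, and the Namalwa comparison 62.7%, 95.5% and 97.0% with 5. The list test recovered 3 of 3 lists shifted by 1 (log2) with 0 false calls. The simulated genes were independent, so this says nothing on lists whose genes vary together or on smaller shifts. The simulated lines were independent too, so the recovery and false calls of the PCM comparison do not cover PCM lines that are nearly alike. Alternatives were each array as a replicate, line as a random block, array 1 or array 2 alone, a second quantile normalization, centring on the 75th percentile, only probe sets above the median level, no probe sets of the _x_at and _s_at type, eBayes with trend and robust, stricter thresholds, the authors' deposited table, and each line or array left out in turn. For lists they also included an estimated correlation, the fry test and the mean of a gene's probe sets, and for the B-cell lines the replicate number as a block and a fit on the 4 SU-DHL arrays. The averaged L363 and U266 arrays, SU-DHL6 array 2 left out, and the hybridisation control level as a covariate were chosen after seeing the data.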

Results

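The series held 9 Affymetrix Human Genome arrays of 6 human cell lines. The B-cell group had 3 lines with 2 arrays each: Namalwa, from a Burkitt lymphoma, and SU-DHL4 and SU-DHL6, from diffuse large B-cell lymphomas. The plasma cell myeloma (PCM) group had 3 lines with 1 array each: L363, from a plasma cell leukaemia, and U266 and LP1, from myelomas. The labels set PCM lines against B-cell lines, and the series title ties that contrast to plasma cell features of classical Hodgkin lymphoma. With 3 lines per group and 4 residual degrees of freedom, the number of arrays limited the precision of every estimate, and only large or very even differences could pass the test. RMA values carry no detection call, so a low value was not read as absence.

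Arrays of the same B-cell line lay closest together, with a standard deviation of the log2 difference of 0.22 to 0.35. Different B-cell lines gave 0.47 to 0.56, and arrays of different groups gave 0.64 to 0.79. The array labelled U266 differed from the L363 array by 0.32, less than the SU-DHL6 duplicates (0.35) but more than those of Namalwa (0.22) and SU-DHL4 (0.24), while LP1 stood 0.55 from each of them. The PCM group may therefore hold fewer than 3 independent lines, and each PCM result has to be read with that in mind. L363 and U266 differed over 4-fold at 40 probe sets, against 1 (Namalwa), 2 (SU-DHL4) and 35 (SU-DHL6) in the duplicates and at least 180 between B-cell lines.

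**Figure D1:**
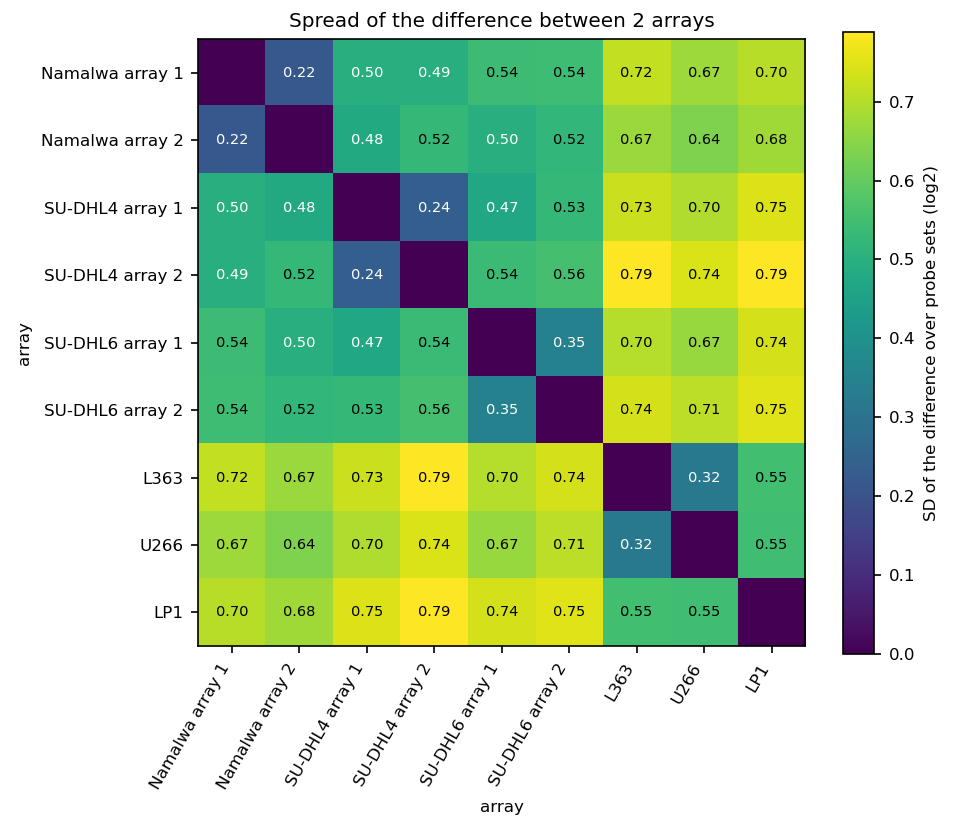
Standard deviation over probe sets of the log2 difference between each pair of the 9 arrays. The L363 and U266 arrays (0.32) lie closer than the SU-DHL6 duplicates (0.35) but not than the other duplicates, and pairs across the groups lie at 0.64 to 0.79.

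Many genes of mature B cells were lower in PCM lines than in B-cell lines, and some plasma cell genes were higher. By limma, 619 of 22215 probe sets changed (adjusted p under 0.05), 249 of them higher in PCM lines, from 187 genes, and 370 lower, from 285 genes. The excess of lower calls depended on scaling, with 347 higher and 355 lower when arrays were centred on the 75th percentile, and 249 and 288 after a second quantile normalization. For all 619 the 3 PCM values lay on 1 side of the 3 B-cell line values. The same was true of 6275 (28.2%) of all tested probe sets. With 6 independent lines 10% would be met by chance, and more if L363 and U266 count as 1 line. The median absolute difference among changed probe sets was 1.23 (log2), the smallest 0.38, and 397 changed at least 2-fold. The authors' deposited table, which treats each array as a replicate, had 2189 probe sets with an adjusted p under 0.05, among them 607 of the 619. Single lines weighed on the count: it was 131 without L363, 149 without SU-DHL4, 192 without U266, 313 without SU-DHL6, 327 without Namalwa and 897 without LP1. Without LP1 the PCM group was L363 and U266 alone, which may be 1 line. Their spread may then be too small, so a call found or kept only without LP1 carries little weight. Averaging the L363 and U266 arrays as 1 line, an alternative chosen after seeing the data, left 184, and 10 of the 24 genes named for the largest differences kept their call. Other choices moved it to 1567 (9 arrays with line as a random block), 271 (no probe sets of the _x_at and _s_at type, which may hybridise to several transcripts), 75 (adjusted p under 0.01) and 1740 (9 arrays with the hybridisation control level as a covariate, chosen after seeing the data). None of the 619 turned direction in any of these fits. Where lines were left out or averaged, the separation of the 3 PCM values fixed this in advance. With each array counted, line as a random block, filtered probe sets or a stricter threshold, the differences equalled those of the main fit. Direction could not turn there either. Only fits that rescaled values, dropped an array of a B-cell line or added the covariate could turn it.

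The deepest falls in PCM lines were in genes of germinal centre and mature B cells. RGS13, a G-protein regulator of germinal centre B cells, fell by 5.99 (log2, SE 0.46, adjusted p = 0.00788). BCL6, the repressor at the core of the germinal centre programme, fell by 5.02 (SE 0.22, adjusted p = 0.00222). CD20, encoded by MS4A1, fell by 5.54 (SE 0.66, adjusted p = 0.0206), and by 5.38 (SE 0.57, adjusted p = 0.0152) at its brightest probe set. PTPRC, which encodes the leukocyte antigen CD45, dropped by 5.43 (SE 0.25, adjusted p = 0.00272), from a mean of 10.11 (SD 0.49) in B-cell lines to 4.69 (SD 0.13). CD79A, the signalling partner of the B-cell receptor, fell by 4.65 (SE 0.18, adjusted p = 0.00167). Its partner CD79B fell by 3.23 (SE 0.33, adjusted p = 0.0145). PAX5, which commits cells to the B lineage, fell by 4.48 (SE 0.15, adjusted p = 0.00160) at its brighter probe set, and did not move at its other one (0.01, adjusted p = 0.968). SPIB, an ETS factor of B cells that plasma cells switch off, fell by 3.04 (SE 0.20, adjusted p = 0.00564). The surface antigens CD52 and CD37 fell by 4.85 (SE 0.34, adjusted p = 0.00629) and 4.81 (SE 0.37, adjusted p = 0.00817). TCL1A, an AKT coactivator of B cells, fell by 4.89 (SE 0.49, adjusted p = 0.0130). SWAP70, a B-cell guanine nucleotide exchange factor, fell by 4.82 (SE 0.46, adjusted p = 0.0125), although 1 of its 3 probe sets did not pass (-0.60). Less studied genes completed the list. These were OSBPL10, a lipid-binding protein (fell by 4.62, SE 0.54, adjusted p = 0.0203), SEL1L3, a membrane protein (fell by 4.58, SE 0.44, adjusted p = 0.0125), and RGCC, a cell cycle regulator (fell by 4.51, SE 0.41, adjusted p = 0.0118). OSBPL10 fell at 1 of 3 probe sets, and the others did not pass (0.11, adjusted p = 0.613, and 0.22, adjusted p = 0.346).

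RGS13, BCL6, PTPRC, CD79A, PAX5, SPIB, CD52 and CD37 kept their call whichever line was left out, with adjusted p at most 0.0467. CD79B lost it without SU-DHL6 or L363 (adjusted p from 0.000297 to 0.0578 over its alternatives). MS4A1 lost it without SU-DHL4, SU-DHL6 or U266 (0.000544 to 0.0797). TCL1A (0.000337 to 0.0711) and SWAP70 (0.000255 to 0.0691) lost it without L363 or U266. OSBPL10 (0.000778 to 0.0910) and SEL1L3 (0.000288 to 0.0632) lost it without SU-DHL4, L363 or U266, and RGCC (0.000310 to 0.0630) without L363. With L363 and U266 averaged, TCL1A, SWAP70, OSBPL10, SEL1L3 and RGCC lost it too.

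**Figure D2:**
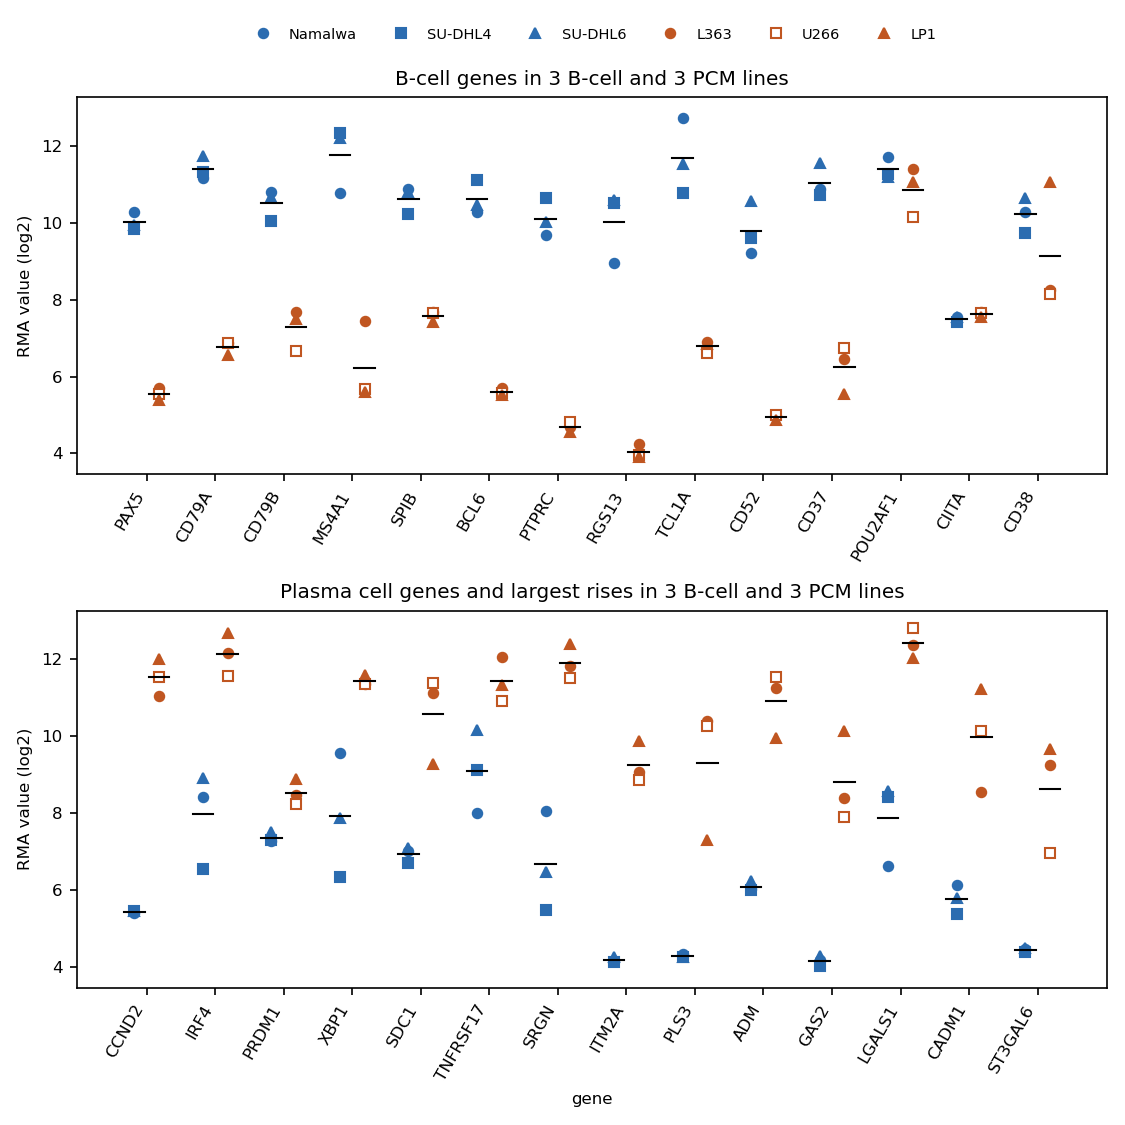
RMA values (log2) of B-cell genes, upper panel, and of plasma cell genes and the largest rises, lower panel; each point is 1 cell line (blue, B-cell lines as the mean of 2 arrays; orange, PCM lines) and each bar the mean of 3 lines. PTPRC had a mean of 10.11 in B-cell lines and 4.69 in PCM lines, while POU2AF1 and CD38 overlapped.

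By camera, 4 gene lists of B-cell function were lower in PCM lines at the preset correlation, and 1 of them also with an estimated one. Of the 18 B-cell identity genes measured, 9 fell over all probe sets and 15 when adjusted over the list alone, with a median difference of -2.72 (camera adjusted p = 3.24e-16, adjusted p = 0.0516 with an estimated correlation). VPREB3, a B-cell surrogate light chain gene, fell by 3.49 (SE 0.12, adjusted p = 0.00160), and BLNK, the adaptor below the B-cell receptor, fell by 4.26 (SE 0.26, adjusted p = 0.00540). B-cell receptor signalling genes followed, with 8 of 20 lower, 14 adjusted over the list alone (median -1.86, adjusted p = 2.85e-13, adjusted p = 0.0366 with an estimated correlation). Among them the kinase gene SYK fell by 3.20 (SE 0.23, adjusted p = 0.00675) at 1 of 2 probe sets (the other -1.85, adjusted p = 0.0628). Germinal centre genes fell at 7 of 12 members, 9 adjusted over the list alone (median -2.06, adjusted p = 1.69e-10, adjusted p = 0.0516 with an estimated correlation). The elongation factor gene ELL3 fell by 3.10 (SE 0.19, adjusted p = 0.00540) and the chromatin gene BCL7A fell by 2.85 (SE 0.25, adjusted p = 0.0106). Among B-cell transcription factors 4 of 16 fell, 8 adjusted over the list alone (median -1.22, adjusted p = 2.65e-09, adjusted p = 0.0649 with an estimated correlation). IRF8, which supports germinal centre B cells, dropped by 4.37 (SE 0.27, adjusted p = 0.00540), and SPI1, the ETS factor PU.1, dropped by 1.48 (SE 0.24, adjusted p = 0.0441). Over all alternatives, fits on 9 arrays included, these 4 lists had adjusted p from 6.02e-51 to 0.0649. Of the genes named for these lists, SPI1 lost its call when a line was left out, in every case but LP1 (0.00330 to 0.128), and CD79B as given above. SPI1 also lost it with L363 and U266 averaged and with array 2 alone of each B-cell line.

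The largest rise in PCM lines was in CCND2, a D-type cyclin that many myelomas express. CCND2 rose by 6.10 (log2, SE 0.24, adjusted p = 0.00167), from 5.43 (SD 0.04) in B-cell lines to 11.54 (SD 0.47), and rose at each of its 3 probe sets. ITM2A, a membrane protein gene of lymphocytes, rose by 5.09 (SE 0.27, adjusted p = 0.00444), and ADM, which encodes the vasodilator adrenomedullin, rose by 4.83 (SE 0.42, adjusted p = 0.0106). The secretory granule proteoglycan gene SRGN rose by 5.25 (SE 0.67, adjusted p = 0.0244), and LGALS1, which encodes galectin-1, rose by 4.54 (SE 0.56, adjusted p = 0.0228). The small heat shock gene HSPB1 rose by 4.08 (SE 0.48, adjusted p = 0.0200), the zinc finger gene ZBTB38 by 4.03 (SE 0.48, adjusted p = 0.0206). GAS2, a gene of growth-arrested cells, rose by 4.64 (SE 0.58, adjusted p = 0.0230). Closer to the threshold were the actin-bundling gene PLS3 (5.03, SE 0.85, adjusted p = 0.0484), the adhesion gene CADM1 (4.21, SE 0.68, adjusted p = 0.0430) and the sialyltransferase gene ST3GAL6 (4.17, SE 0.71, adjusted p = 0.0484). Second probe sets were weaker for SRGN (4.75, adjusted p = 0.0505), for CADM1 (2.91, adjusted p = 0.0572, and 1.70, adjusted p = 0.149) and for 2 of 4 of ST3GAL6 (0.39 and 0.19), and these did not pass. The remaining ST3GAL6 probe set did pass (3.75, SE 0.38, adjusted p = 0.0141). The alternatives below are for the probe set named first. CCND2 and ITM2A kept their call whichever line was left out. ADM lost it only without L363 (adjusted p from 5.90e-05 to 0.0578 over its alternatives). SRGN (0.00282 to 0.107) lost it without SU-DHL4, SU-DHL6, L363 or U266. LGALS1 (0.00198 to 0.102) and HSPB1 (0.00200 to 0.0892) lost it without SU-DHL4, L363 or U266. ZBTB38 (0.000868 to 0.0898) and GAS2 (0.000257 to 0.0918) kept it only without U266 or LP1, and CADM1 (0.00125 to 0.142) only without L363 or LP1. PLS3 (0.000517 to 0.160) kept it, among fits leaving out 1 line, only without LP1, and ST3GAL6 (0.00136 to 0.174) only without U266. With L363 and U266 averaged, only CCND2, ITM2A and ADM of these rises kept their call. PLS3 and ST3GAL6 also lost it with array 2 alone of each B-cell line, after a second quantile normalization and without probe sets of the _x_at and _s_at type. ST3GAL6 lost it with array 1 alone and HSPB1 with array 2 alone.

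Some regulators and markers of plasma cells rose and others did not pass. IRF4, which drives plasma cell differentiation and on which myeloma cells depend, rose by 4.18 (SE 0.67, adjusted p = 0.0425). SDC1, which encodes the plasma cell antigen CD138, rose by 3.66 (SE 0.57, adjusted p = 0.0402). PRDM1, which encodes the repressor BLIMP1, rose by 1.17 (SE 0.19, adjusted p = 0.0415). ELL2, an elongation factor for secreted immunoglobulin, rose by 3.74 (SE 0.22, adjusted p = 0.00540), the homing receptor CCR10 by 3.68 (SE 0.29, adjusted p = 0.00862). CAV1, the caveolin of cell membranes, rose by 2.88 (SE 0.27, adjusted p = 0.0118). At other probe sets SDC1 (2.65, adjusted p = 0.0587), CAV1 (1.77, adjusted p = 0.0987), ELL2 (0.08, adjusted p = 0.601) and 1 of 3 of IRF4 (0.10, adjusted p = 0.534) did not pass. CD27, a receptor of memory B cells and normal plasma cells, moved the other way and fell by 3.61 (SE 0.15, adjusted p = 0.00197). In the list of plasma cell factors and surface markers 7 of 20 genes rose and 1 fell, 15 and 1 adjusted over the list alone (median 1.73, camera adjusted p = 4.74e-07, adjusted p = 0.0871 with an estimated correlation, 2.51e-15 to 0.0871 over the alternatives). XBP1, the factor of the secretory programme, and TNFRSF17, which encodes BCMA, did not pass the test at 3.51 (SE 0.79, adjusted p = 0.0922) and 2.35 (SE 0.59, adjusted p = 0.116), although all 3 PCM values lay above all B-cell values. XBP1 passed without Namalwa, with adjusted p = 0.0337 (0.0188 to 0.252 over its alternatives). XBP1 and TNFRSF17 (0.0278 to 0.313) passed when each of the 9 arrays was a replicate or line was a random block, and TNFRSF17 with the hybridisation covariate. In the replicate and block fits their differences were unchanged. The 2 arrays of a line are not 2 lines, so passing there adds no support. The B-cell coactivator gene POU2AF1 (-0.54, SE 0.35, adjusted p = 0.431), the class II activator CIITA (0.13, SE 0.08, adjusted p = 0.414) and the ectoenzyme gene CD38 (-1.07, SE 0.83, adjusted p = 0.502) did not pass either. CD38 was lower only without LP1 (adjusted p = 0.0376, up to 0.815 over its alternatives), where the PCM group was L363 and U266 alone. ELL2, CCR10 and CD27 kept their call whichever line was left out. CAV1 lost it without SU-DHL4 or L363 (7.58e-05 to 0.0618). SDC1 (0.00101 to 0.151) and PRDM1 (0.00108 to 0.140) kept it only without LP1, and IRF4 (0.00344 to 0.157) only without SU-DHL4. With L363 and U266 averaged, SDC1 (0.117), PRDM1 (0.0880) and IRF4 (0.117) lost it too, and PRDM1 did with array 2 alone of each B-cell line (0.0501).

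A minority of the genes for making and exporting glycoproteins rose modestly in PCM lines. The signal peptidase genes SPCS1 and SEC11A rose by 1.27 (SE 0.15, adjusted p = 0.0194) and 1.05 (SE 0.12, adjusted p = 0.0206), the translocon gene SEC61A1 by 1.12 (SE 0.16, adjusted p = 0.0322) and the cargo receptor gene TMED10 by 0.74 (SE 0.09, adjusted p = 0.0244). Of 26 N-glycosylation genes 4 rose. MAN2A1, a Golgi mannosidase, rose by 2.12 (SE 0.31, adjusted p = 0.0367), RPN2, part of the oligosaccharyl transferase, by 0.84 (SE 0.12, adjusted p = 0.0322). The glucosidase gene GANAB rose by 0.73 (SE 0.12, adjusted p = 0.0472) at 1 of 2 probe sets, and DPM2, of dolichol mannose synthesis, by 0.52 (SE 0.07, adjusted p = 0.0239). In the unfolded protein response the chaperone genes PDIA6 and HYOU1 rose by 0.92 (SE 0.15, adjusted p = 0.0423) and 0.86 (SE 0.14, adjusted p = 0.0444). None of these 10 genes kept its call without L363, and over the fits that left out 1 line their adjusted p ran from 0.00875 (MAN2A1) to 0.154 (PDIA6). All 10 also lost it with L363 and U266 averaged. With trend and robust eBayes PDIA6, HYOU1, TMED10, DPM2 and GANAB lost it, and with array 1 alone of each B-cell line HYOU1, TMED10, DPM2 and GANAB. With array 2 alone PDIA6, HYOU1, RPN2 and MAN2A1 lost it, and without SU-DHL6 array 2 HYOU1, TMED10 and DPM2. The secretory pathway list was shifted upwards (4 of 41 higher, 7 higher and 1 lower adjusted over the list alone, median 0.32, camera adjusted p = 0.0173). So were the lists of N-glycosylation (4 of 26 higher, 10 adjusted over the list alone, median 0.60, adjusted p = 1.52e-05) and unfolded protein response genes (2 of 24 higher, 10 higher and 1 lower adjusted over the list alone, median 0.68, adjusted p = 0.000479). None passed with the correlation estimated: adjusted p = 0.146 with an estimated correlation for the secretory list, 0.174 for N-glycosylation and 0.158 for the unfolded protein response. Across all alternatives they ranged from 3.65e-05 to 0.146, from 3.03e-08 to 0.174 and from 8.64e-06 to 0.201. The secretory list also lost its shift without LP1 (0.0855), without SU-DHL6 (0.0642) and without probe sets of the _x_at and _s_at type (0.0575). The unfolded protein response lost its shift in that last fit (0.201).

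**Figure D3:**
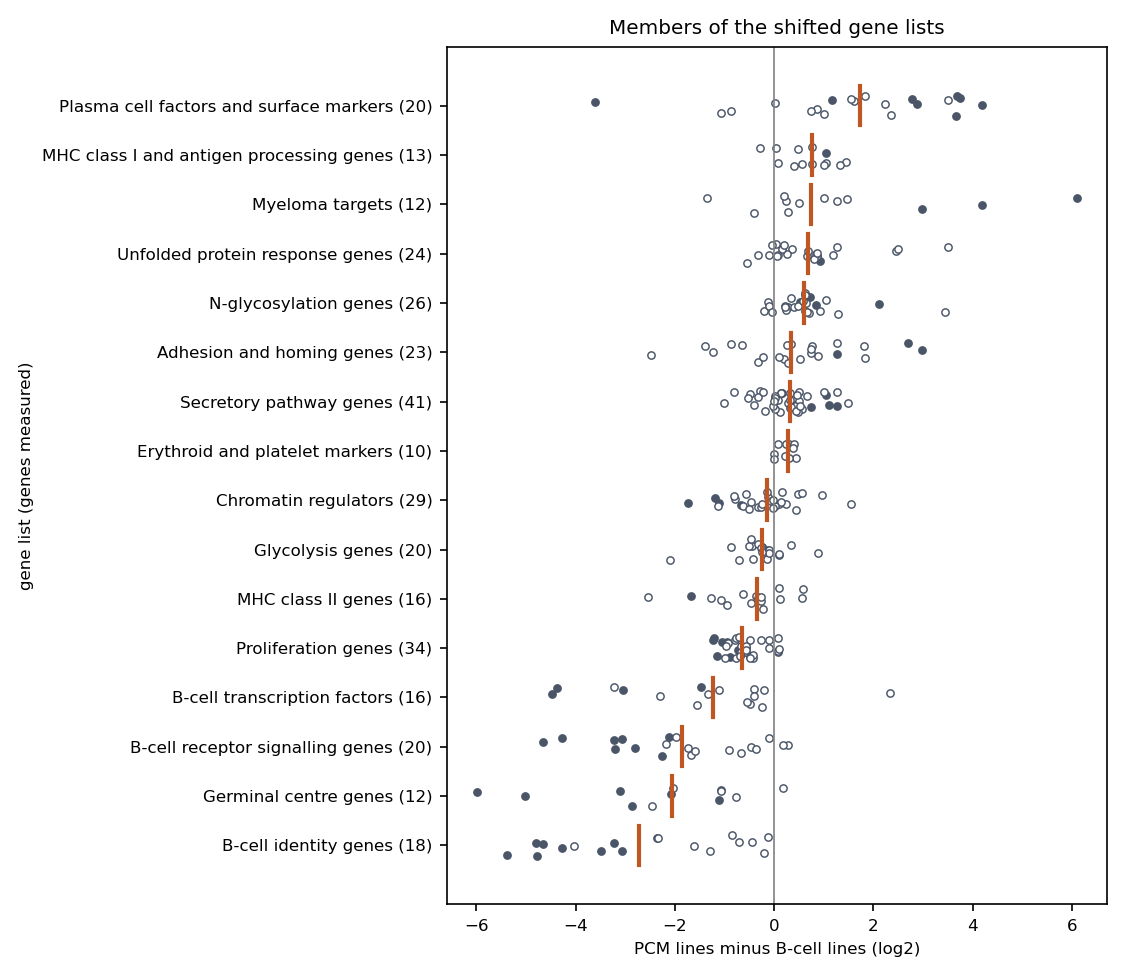
Differences between PCM and B-cell lines (log2, 3 lines each) for every measured gene of the 16 shifted lists; filled points passed adjusted p under 0.05 over all probe sets and bars mark list medians. B-cell identity genes had the lowest median, -2.72, and plasma cell factors the highest, 1.73.

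Of 12 myeloma oncogene targets, MAF and FGFR3 stood out in LP1, a single array that allows no test. MAF, a transcription factor activated in some myelomas, reached 9.23 (log2) in LP1 and at most 5.30 in every other line, with less contrast at its weakest probe set (5.61 against at most 4.73). FGFR3, a receptor gene of a recurrent myeloma translocation, reached 8.48 in LP1 against at most 6.34 elsewhere. Its second probe set barely set LP1 apart (5.94, against 5.72 in L363 and 5.61 in U266). CCND1, the cyclin that U266 is known to express from a rearranged locus, stayed at 4.93 on the array labelled U266, within 0.04 of the L363 array. The chemokine receptor gene CCR1, a MAF target, rose in PCM lines by 2.98 (SE 0.28, adjusted p = 0.0118). Among PCM lines CCR1 was lowest in LP1, the line with high MAF, at 9.11 against 10.00 in L363 and 10.12 in U266. With CCND2 and IRF4 it made up the 3 of 12 list members that rose, also 3 adjusted over the list alone (median 0.75, camera adjusted p = 0.00415, adjusted p = 0.174 with an estimated correlation, 4.70e-14 to 0.174 over the alternatives). This list lost its shift without probe sets of the _x_at and _s_at type (0.0931). FRZB, a WNT antagonist gene, did not pass (0.29, SE 0.12, adjusted p = 0.254). Adhesion and homing genes were shifted upwards with 3 of 23 higher, 8 adjusted over the list alone (median 0.33, adjusted p = 0.0157, adjusted p = 0.147 with an estimated correlation, 6.62e-06 to 0.147 over the alternatives). They lost the shift without SU-DHL6 (0.0729), without probe sets of the _x_at and _s_at type (0.0706) and with arrays centred on the 75th percentile (0.0628). The tetraspanin gene CD151 rose by 1.26 (SE 0.11, adjusted p = 0.0106) and kept its call whichever line was left out. SELPLG, the selectin ligand gene, rose by 2.71 (SE 0.25, adjusted p = 0.0118). SELPLG (0.000122 to 0.0533) lost its call without SU-DHL4 or U266, and CCR1 (8.18e-05 to 0.0618) without SU-DHL4 or L363.

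**Figure D4:**
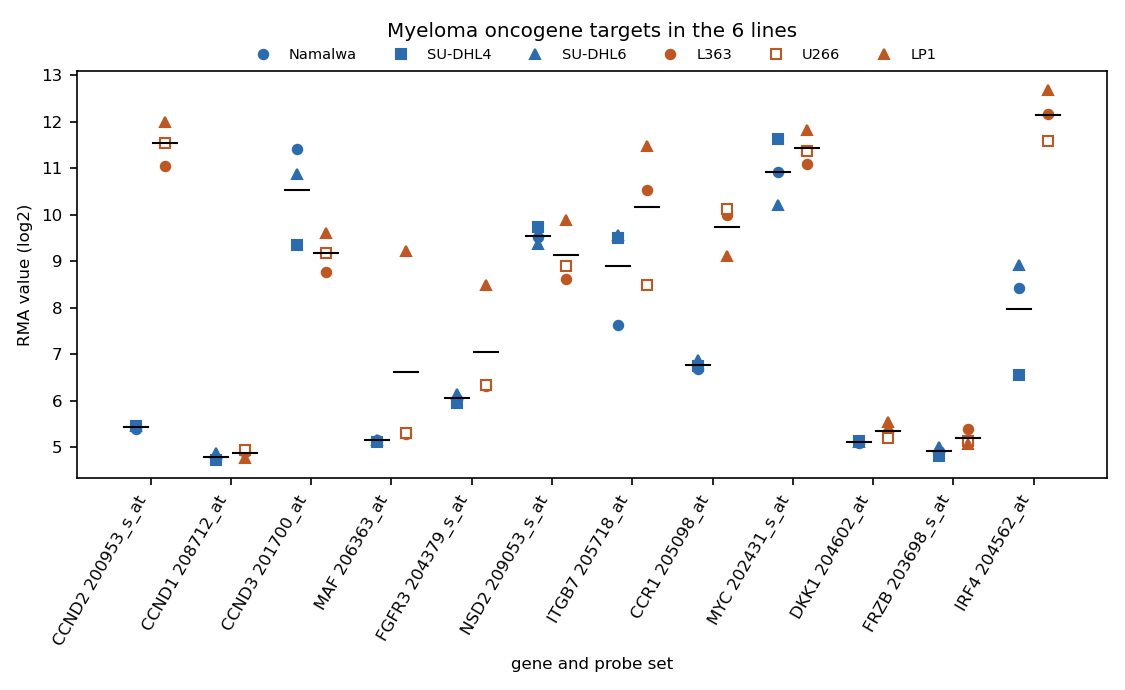
RMA values (log2) of 12 myeloma oncogene targets in the 3 B-cell lines (blue) and 3 PCM lines (orange), with the mean of each group as a bar. MAF (9.23) and FGFR3 (8.48) stood out in LP1 alone, and CCND2 was high in all 3 PCM lines.

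Proliferation genes were lower in PCM lines, evenly rather than deeply. In this list 30 of 34 had a negative difference, 8 fell over all probe sets and 17 adjusted over the list alone (median -0.65, camera adjusted p = 2.50e-13, adjusted p = 0.0649 with an estimated correlation, 1.76e-15 to 0.0649 over the alternatives). TOP2A, the topoisomerase of dividing cells, fell by 1.23 (SE 0.12, adjusted p = 0.0139; second probe set -1.67, adjusted p = 0.0559), the spindle checkpoint kinase gene BUB1B by 1.21 (SE 0.14, adjusted p = 0.0177), and the mitotic activator CDC20 by 0.94 (SE 0.12, adjusted p = 0.0272). The spindle motor gene KIF11 fell by 0.90 (SE 0.12, adjusted p = 0.0261). TOP2A (0.000377 to 0.0606) lost its call without SU-DHL4, L363 or U266. BUB1B (0.00124 to 0.0663), KIF11 (0.000605 to 0.105) and CDC20 (0.00820 to 0.127) kept theirs only without LP1. Chromatin regulators of the Polycomb and Trithorax type fell at 4 of 29 genes (4 higher and 8 lower adjusted over the list alone, median -0.14, adjusted p = 0.0266, adjusted p = 0.395 with an estimated correlation, 0.00870 to 0.395 over the alternatives). The shift was lost without L363 (0.140), after a second quantile normalization (0.322), among probe sets above the median level (0.127) and with fry (0.127). Of 10000 random lists matched on level, 10.2% had a median as low, so the median alone did not set this list apart. In this list the deacetylase gene HDAC1 fell by 1.73 (SE 0.22, adjusted p = 0.0251), EED and EZH2, of the Polycomb complex that methylates histone H3, by 1.19 (SE 0.17, adjusted p = 0.0339) and 1.10 (SE 0.19, adjusted p = 0.0484; EED not at its second probe set, -0.12), and the DNA methyltransferase gene DNMT1 by 0.67 (SE 0.11, adjusted p = 0.0472). HDAC1 (0.00114 to 0.109) kept its call without Namalwa or LP1, EED (0.00137 to 0.101) and DNMT1 (0.00367 to 0.148) only without LP1, and EZH2 (0.00441 to 0.139) in no fit that left out a line. With L363 and U266 averaged, these 4 and BUB1B, KIF11 and CDC20 lost their call. KIF11 and CDC20 also lost it with trend and robust eBayes, and CDC20 with array 2 alone of each B-cell line. DNMT1 and EZH2 lost it with array 1 alone, after a second quantile normalization and with trend and robust eBayes. DNMT1 lost it with arrays centred on the 75th percentile and EZH2 with array 2 alone.

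Smaller list shifts rested on few or no single genes. The MHC class II list was lower (1 of 16, also 1 adjusted over the list alone, median -0.35, camera adjusted p = 0.0434, adjusted p = 0.395 with an estimated correlation, 0.0112 to 0.395 over the alternatives). It lost its shift without L363 (0.350), SU-DHL6 (0.170) or SU-DHL4 (0.0548), and in 7 other alternatives, among them a second quantile normalization (0.161) and probe sets above the median level (0.263). Its changed gene was HLA-DOB, which tempers peptide loading in B cells and fell by 1.68 (SE 0.24, adjusted p = 0.0330), a call kept only without Namalwa among fits leaving out 1 line (0.0149 to 0.117). It was lost with L363 and U266 averaged and with array 2 alone of each B-cell line. The MHC class I and antigen processing list was higher (1 of 13, also 1 adjusted over the list alone, median 0.75, adjusted p = 0.0283, adjusted p = 0.523 with an estimated correlation, 0.00206 to 0.523 over the alternatives). That shift was lost without LP1 (0.335) or SU-DHL4 (0.0712), and without probe sets of the _x_at and _s_at type (0.446). It was also lost with arrays centred on the 75th percentile (0.0628), with line as a random block (0.0733), with the hybridisation covariate (0.0710), with the mean of all probe sets of a gene (0.0530) and with fry. The peptide-trimming gene ERAP1 rose there by 1.05 (SE 0.15, adjusted p = 0.0358) at 1 of 5 probe sets, and lost its call whichever line was left out (0.0184 to 0.158 over all its alternatives), and in 4 other alternatives. Glycolysis genes were lower with no gene past the threshold, 0 of 20 and 0 adjusted over the list alone (median -0.25, adjusted p = 0.00415, adjusted p = 0.308 with an estimated correlation, 0.000745 to 0.308 over the alternatives). They lost the shift after a second quantile normalization (0.105), among probe sets above the median level, without those of the _x_at and _s_at type (0.0575) and with fry (0.115). Of 10000 random lists matched on level, 4.14% had a median as low, and the list median lay within the central 95% of them (-0.27 to 0.10). The largest difference, in the hexokinase gene HK1, did not pass (-2.10, SE 0.44, adjusted p = 0.0756), but it did in 5 alternatives, among them without Namalwa. Erythroid and platelet markers, entered as markers of other cell types, were higher with 0 of 10 genes past the threshold and 0 adjusted over the list alone (median 0.27, adjusted p = 0.00908, adjusted p = 0.395 with an estimated correlation, 0.00590 to 0.395 over the alternatives). They lost the shift without probe sets of the _x_at and _s_at type (0.210), with line as a random block (0.0910) and with the hybridisation covariate (0.0536). Of random lists, 0.87% of 10000 matched on level had a median as high.

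Lists of other programmes did not pass the test. PIM2, a survival kinase gene below IL6, rose by 1.56 (SE 0.24, adjusted p = 0.0402), kept only without Namalwa (0.00480 to 0.117), within an IL6 and JAK-STAT list that did not shift (19 genes, adjusted p = 0.115). That list was higher without Namalwa (adjusted p = 0.0488), with only array 1 of each B-cell line (0.0366) and with fry (0.00803, up to 0.308 over its alternatives). TRIM22, an antiviral gene, fell by 3.96 (SE 0.24, adjusted p = 0.00540) whichever line was left out. Interferon response genes (31, adjusted p = 0.115) were lower as a list without SU-DHL4 (0.0166) or SU-DHL6 (0.0202), and with arrays centred on the 75th percentile (0.0462; 0.0166 to 0.726 over the alternatives). NF-kB genes (23, adjusted p = 0.0605) were lower in 4 alternatives. These were without SU-DHL4 (0.00433), without probe sets of the _x_at and _s_at type (0.00982), with arrays centred on the 75th percentile (0.0249) and with only array 1 of each B-cell line (0.0499, up to 0.670 over the alternatives). Hodgkin lymphoma markers (23, adjusted p = 0.161), in which LGALS1 alone rose, were higher without LP1 (0.0298, up to 0.643 over the alternatives). The kinase gene LCK, of T cells and some B-cell lymphomas, fell by 4.17 (SE 0.41, adjusted p = 0.0128), lost without SU-DHL4, L363 or U266 (0.000318 to 0.0691), while T and NK cell markers did not shift (21, adjusted p = 0.423). Among 10 cell cycle inhibitors (adjusted p = 0.298) CDKN1B, which encodes p27, rose by 2.48 (SE 0.39, adjusted p = 0.0402) and the retinoblastoma gene RB1 fell by 2.21 (SE 0.36, adjusted p = 0.0453) at 1 of 2 probe sets. CDKN1B kept its call only without Namalwa (0.00432 to 0.137) and RB1 in no such fit (0.00383 to 0.169). SLC1A5, a glutamine transporter gene, rose by 0.57 (SE 0.10, adjusted p = 0.0492), kept only without LP1 (0.0330 to 0.158), in an unshifted list of amino acid and ATF4 target genes (26, adjusted p = 0.562). Ribosomal protein genes (31, adjusted p = 0.115) were lower without U266 (0.0427, up to 0.992), and oxidative phosphorylation genes (34, adjusted p = 0.415) were higher after a second quantile normalization (0.00296, up to 0.809). Nor did the test pass for immunoglobulin genes (8, adjusted p = 0.298), apoptosis regulators (22, 0.845), cholesterol synthesis genes (19, 0.773), myeloid markers (18, 0.115) or epithelial, fibroblast and endothelial markers (20, 0.154). For immunoglobulin, ribosomal, apoptosis, ATF4 target and T and NK cell genes the mean and the median of the list had opposite signs in the main fit, so that no direction was read from that fit. Of the single genes in this paragraph only TRIM22 kept its call with L363 and U266 averaged. PIM2 and SLC1A5 also lost theirs with array 2 alone of each B-cell line. RB1 and SLC1A5 lost theirs with array 1 alone and without SU-DHL6 array 2. SLC1A5 lost it with line as a random block, among probe sets above the median level and with trend and robust eBayes.

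SU-DHL6 and SU-DHL4, 2 lines of the same lymphoma type, had their largest differences in IGHM, TUBB2B and MEF2C. IGHM, the constant gene of IgM, was 5.93 higher in SU-DHL6 (log2, SE 0.16, adjusted p = 0.000323) and higher at 2 of its 5 probe sets. The others, of the _x_at type, did not pass (-0.44 to 0.24), nor did the immunoglobulin list (2 of 8 higher and 1 lower, adjusted p = 0.134). TUBB2B, a tubulin gene of neurons, was 5.12 higher (SE 0.23, adjusted p = 0.000764) and VIM, the intermediate filament vimentin, 4.67 higher (SE 0.27, adjusted p = 0.00139). UCHL1, a deubiquitinase gene of germinal centre cells, was 4.45 higher (SE 0.16, adjusted p = 0.000594), and the homeobox gene CUX2 4.07 higher (SE 0.26, adjusted p = 0.00190). MEF2C, a factor for B-cell receptor responses, was lower by -4.70 (SE 0.25, adjusted p = 0.00128), with the corepressor gene CTBP2 (-4.02, SE 0.12, adjusted p = 0.000343), the adhesion gene CD99 (-3.85, SE 0.16, adjusted p = 0.000716), the coactivator gene ZMIZ1 (-3.80, SE 0.31, adjusted p = 0.00297) and the apoptosis inhibitor gene FAIM (-3.78, SE 0.17, adjusted p = 0.000764). IRF4 was 2.37 higher in SU-DHL6 (SE 0.16, adjusted p = 0.00220) at 1 of 3 probe sets and XBP1 1.53 higher (SE 0.21, adjusted p = 0.0125), so that these plasma cell regulators also varied within lymphoma lines. TNFRSF17 (1.04, SE 0.17, adjusted p = 0.0240) and CD38 (0.92, SE 0.19, adjusted p = 0.0461) were higher and BCL6 lower (-0.64, SE 0.11, adjusted p = 0.0252). By limma 1892 probe sets differed between the 2 lines, 833 higher and 1059 lower in SU-DHL6, 877 of them at least 2-fold. With arrays centred on the 75th percentile the balance turned, to 1069 higher and 1052 lower. The spread here was that between 2 arrays of 1 line, and nothing in the labels says that duplicates were separate cultures, so the result holds for these arrays only. The count was 319 without SU-DHL4 array 2, 540 without SU-DHL4 array 1, 852 without the Namalwa arrays and 940 without probe sets of the _x_at and _s_at type. ZMIZ1 lost its call without SU-DHL4 array 2 (0.00139 to 0.0540), XBP1 without either SU-DHL4 array (0.00684 to 0.117), and BCL6 (0.0220 to 0.166) and CD38 (0.00988 to 0.245) without any 1 array of Namalwa or SU-DHL4. TNFRSF17 (0.0123 to 0.0804) lost it without either Namalwa array, SU-DHL4 array 1 or SU-DHL6 array 2. On the 4 SU-DHL arrays alone BCL6 (0.0786), CD38 (0.116) and TNFRSF17 (0.0804) did not pass.

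List tests between the B-cell lines were added after the data were examined. SU-DHL6 array 2 had the highest 3' minus 5' differences of the GAPDH (0.44) and ACTB (-0.19) controls among the B-cell arrays, as RNA degradation or shortened cDNA would give, and each SU-DHL6 result has to be read with that in mind. Of markers of other cell types, the fibroblast genes DCN (-2.70, adjusted p = 0.000416) and THY1 (-2.22, adjusted p = 0.00186) were lower in SU-DHL6, in a list that did not pass (20 genes, adjusted p = 0.930). Cholesterol synthesis genes were higher in SU-DHL6 (6 of 19, 7 adjusted over the list alone, median 0.31, camera adjusted p = 0.00782, adjusted p = 0.506 with an estimated correlation, 0.000759 to 0.506 over the alternatives). They were led by the sterol isomerase gene EBP (2.61, adjusted p = 0.000475), which was higher at 2 probe sets and lower at another (-1.37, adjusted p = 0.0205). Proliferation genes were lower (4 of 34, 6 lower and 3 higher adjusted over the list alone, median -0.19, adjusted p = 0.00782, adjusted p = 0.506 with an estimated correlation, 0.00335 to 0.506 over the alternatives), a shift lost without SU-DHL6 array 2 (0.0570) and among probe sets above the median level (0.0611). The cyclin gene CCNA2 stood at -1.45. MHC class I genes were higher (6 of 13, 6 higher and 1 lower adjusted over the list alone, median 0.49, adjusted p = 0.0255, adjusted p = 0.506 with an estimated correlation, 0.0114 to 0.744 over the alternatives). HLA-C (2.74) and HLA-B (2.27) led them, but they lost the shift without SU-DHL4 array 1 (0.0954) or SU-DHL6 array 2 (0.0522), and with arrays centred on the 75th percentile (0.0566). The highest value, 0.744, came without probe sets of the _x_at and _s_at type, and HLA probe sets may cross-hybridise or miss an allele. NF-kB genes were higher (8 of 23 higher and 1 lower, 10 and 1 adjusted over the list alone, median 0.38, adjusted p = 0.0312, adjusted p = 0.533 with an estimated correlation, 0.0159 to 0.533 over the alternatives). They included NFKBIE, an inhibitor of NF-kB (1.27), and lost the shift without SU-DHL4 array 2 (0.0883) or SU-DHL6 array 2 (0.0810). The shift was also lost without probe sets of the _x_at and _s_at type (0.257) and with arrays centred on the 75th percentile (0.0575). B-cell transcription factors were lower (1 of 16, 1 lower and 1 higher adjusted over the list alone, median -0.33, adjusted p = 0.0255, adjusted p = 0.506 with an estimated correlation, 0.0149 to 0.506 over the alternatives). The 1 gene past the threshold was MEF2C. The shift was lost without SU-DHL4 array 1 (0.0536) or SU-DHL6 array 1 (0.200), among probe sets above the median level (0.191) and without those of the _x_at and _s_at type (0.269).

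Namalwa differed from the 2 SU-DHL lines in single genes of many kinds. YBX3, a cold shock domain gene, was 5.90 higher in Namalwa (log2, SE 0.17, adjusted p = 0.000377), PLAC8, a cysteine-rich protein gene of lymphoid cells, 5.79 higher (SE 0.12, adjusted p = 0.000151) and PRKAR2B, a regulatory subunit of protein kinase A, 5.61 higher (SE 0.24, adjusted p = 0.000571). BMS1P20, a pseudogene inside the lambda light chain locus (4.72, SE 0.13, adjusted p = 0.000377), and SMAD1, a BMP signal transducer (4.11, SE 0.17, adjusted p = 0.000589), were also higher. YBX3 was higher at 2 of 3 probe sets and BMS1P20 at 1 of 2. Lower in Namalwa were KANK1, a cytoskeletal regulator (-3.88, SE 0.12, adjusted p = 0.000459), the endosomal gene NSG1 (-3.87, SE 0.22, adjusted p = 0.00136), the translation initiation gene EIF2S3 (-3.82, SE 0.32, adjusted p = 0.00322), TOX, a nuclear factor of lymphocyte development (-3.38, SE 0.22, adjusted p = 0.00186, not at its second probe set), and the sorting receptor gene SORL1 (-3.16, SE 0.13, adjusted p = 0.000571). XBP1 was 2.48 higher (SE 0.18, adjusted p = 0.00244) and IRF4 0.70 higher (SE 0.14, adjusted p = 0.0390, at 1 of 3 probe sets), with TNFRSF17 (-1.63, SE 0.15, adjusted p = 0.00421), MS4A1 (-1.47, SE 0.15, adjusted p = 0.00579) and BCL6 (-0.50, SE 0.09, adjusted p = 0.0325) lower. The contrast is with the mean of the 2 SU-DHL lines. IRF4 in Namalwa (8.43) lay above SU-DHL4 (6.55) but below SU-DHL6 (8.92). In all 2001 probe sets differed, 1044 higher and 957 lower, 686 at least 2-fold. Lower calls were the more numerous among probe sets above the median level (842 higher, 860 lower) and without those of the _x_at and _s_at type (458 and 487). The Namalwa arrays come from an earlier series of the same group, so line and array batch cannot be told apart in this comparison. The count was 187 and 228 without Namalwa array 1 and 2, 766 and 759 without SU-DHL4 array 1 and 2, and 945 without probe sets of the _x_at and _s_at type. TNFRSF17 (0.00204 to 0.0707) and MS4A1 (0.00325 to 0.0829) lost their call without either Namalwa array, and BCL6 (0.0219 to 0.243) and IRF4 (0.0227 to 0.262) without either array of Namalwa or SU-DHL4.

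Interferon response genes were higher in Namalwa, with 12 of 31 higher, 14 adjusted over the list alone (median 0.29, camera adjusted p = 3.27e-06, adjusted p = 0.357 with an estimated correlation, 4.65e-07 to 0.357 over the alternatives), and led by the antiviral GTPase gene MX1 (2.97). MHC class I genes were higher (8 of 13, also 8 adjusted over the list alone, median 0.69, adjusted p = 3.27e-06, adjusted p = 0.357 with an estimated correlation, 9.77e-07 to 0.725 over the alternatives, the last without probe sets of the _x_at and _s_at type). MHC class II genes were lower (7 of 16 lower and 2 higher, 8 and 2 adjusted over the list alone, median -0.40, adjusted p = 0.00255, adjusted p = 0.357 with an estimated correlation, 0.00126 to 0.357 over the alternatives). HLA-C (2.41) and HLA-B (2.52) led the class I list, and HLA-DMB, which helps peptide loading, the class II list (-1.71). NF-kB genes were higher (4 of 23 higher and 1 lower, 6 and 2 adjusted over the list alone, median 0.17, adjusted p = 0.00898, adjusted p = 0.527 with an estimated correlation, 0.00274 to 0.527 over the alternatives), with the chemokine gene CCL4 at 3.36, but not among probe sets above the median level (0.118). Germinal centre genes were lower (4 of 12 lower and 1 higher, 6 and 1 adjusted over the list alone, median -0.40, adjusted p = 0.0194, adjusted p = 0.643 with an estimated correlation, 0.000141 to 0.643 over the alternatives). RGS13 stood at -1.59, and the list lost the shift without SU-DHL4 array 2 (0.0599) or SU-DHL6 array 2 (0.0702), and among probe sets above the median level (0.341). Immunoglobulin genes were higher (3 of 8 higher and 1 lower, also 3 and 1 adjusted over the list alone, median 0.35, adjusted p = 0.0475, adjusted p = 0.527 with an estimated correlation, 0.0141 to 0.527 over the alternatives). This was lost without Namalwa array 2 (0.127), SU-DHL4 array 2 (0.121) or SU-DHL6 array 2 (0.0702), among probe sets above the median level (0.218) and with arrays centred on the 75th percentile (0.0657). Their probe sets may also cross-hybridise. IGHM, which passed, lay at 12.64 in Namalwa, above SU-DHL4 (7.05) but below SU-DHL6 (12.99).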

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

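Tests on the shared hybridisation batch, on CCND1 as a sign of the U266 label and on the ACTB control were chosen only after the result was seen. Among 70 checks of the 6 B-cell arrays, 5 values lay far from the others relative to the range of the group. Chance would mark about 1 in 20 among independent values. The arrays are duplicates of 3 lines and the checks overlap, so that share does not apply here. On SU-DHL6 array 2 the GAPDH control differed between its 3' and 5' probe sets by 0.44 (log2; 0.442, nearest other array 0.0305), and the ACTB control by -0.19 (nearest -0.56). The mean level of oxidative phosphorylation genes on this array was 10.9 (nearest 11), and that of glycolysis genes 10.9 (nearest 10.6). CIITA had its lowest level, 7.27, on SU-DHL4 array 2 (nearest 7.52).

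SU-DHL6 array 2 stood apart from its duplicate, with a standard deviation of 0.35 between them. RNA degradation or shortened cDNA may account for part of this, since the ACTB control also had its highest 3' minus 5' difference there (-0.19). The difference between the 2 arrays was shared by 2 probe sets of the same gene with a correlation of 0.487, above the Namalwa (0.24) and SU-DHL4 (0.36) duplicates, as differences in expression between the samples could give. These explanations stay open together. Leaving this array out gave 561 changed probe sets between PCM and B-cell lines.

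The arrays labelled L363 and U266 were nearly alike, though 40 probe sets differed over 4-fold, against 1, 2 and 35 in the duplicates. A shared hybridisation batch stays open: Namalwa array 2 and SU-DHL4 array 1, with similarly low hybridisation controls, differed by a standard deviation of 0.48, but they come from different series, so the value says nothing on a shared batch. The same RNA on both arrays was left undecided, with a correlation of 0.542 over 2 probe sets of a gene. The duplicates gave 0.24 (Namalwa), 0.36 (SU-DHL4) and 0.487 (SU-DHL6), and L363 and LP1 gave 0.753. The value was above every duplicate pair, which goes against the same RNA, but not by the margin set in advance. The same line behind both labels stays open. CCND1, which U266 is known to express, differed from the highest other array by only 0.039 at 1 probe set and by -0.17 at the other. Low CCND1 puts the U266 label in question but cannot show that the line is L363. At the first probe set all arrays lay between 4.65 and 4.93, so no array shows that it responds. This was 1 gene, and the test followed the observation. Averaging the 2 arrays as 1 line gave 184 changed probe sets in place of 619.

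Proliferation genes were lower in PCM lines as a list, but not past the threshold with an estimated correlation (adjusted p = 0.0649). A narrower range of values on the PCM arrays was argued against as the whole cause, since the mean difference was -0.44 after a second quantile normalization, against -0.60 before. The level of the probe sets was argued against too, since 0% of 10000 random lists matched on level had a median as low. A lower rate of division in the PCM cultures may be a candidate explanation, as a hypothesis only, and growth was not measured here.

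The splits of the lines are too few for a share under 0.05. Of the 10 splits of the 6 lines into 3 and 3, 1 (the real split) gave 619 changed probe sets, and the highest other gave 0. For gene lists 1 split gave 16, and the others gave 3 to 13, although none of them changed a probe set. At the preset correlation many lists thus shifted in other groupings of these lines too, so the number of shifted lists says little.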

How the results depend on the processing

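Averaged L363 and U266 arrays, SU-DHL6 array 2 left out and the hybridisation covariate were tests chosen only after the result was seen. None of the 619 changed probe sets and none of the 16 shifted lists turned direction, while the means of some unshifted lists crossed 0 (immunoglobulin genes -0.49 to 0.14). For the probe sets this was fixed in advance in fits that left out or averaged lines. Differences equalled the main ones with each array counted, line as a random block, trend and robust eBayes, filtered probe sets or stricter thresholds. Direction was fixed there too. Only fits that rescaled values, dropped an array of a B-cell line or added the covariate could turn it. Against 619 changed probe sets between PCM and B-cell lines, counts were 2189 with each of the 9 arrays as a replicate and in the authors' deposited table, 1567 with line as a random block, 271 without probe sets of the _x_at and _s_at type (fewer tested), 184 with L363 and U266 averaged (fewer lines), 1740 with the hybridisation covariate on 9 arrays, 397 at 2-fold or more and 75 at an adjusted p under 0.01. Leaving out 1 line gave 131 (without L363, 70 higher and 61 lower, against 249 and 370) to 897 (without LP1). The other alternatives gave 423 to 702. Against 16 shifted lists, 1 was left with an estimated correlation and 10 without _x_at and _s_at probe sets, and leaving out 1 line gave 14 to 17. SU-DHL6 against SU-DHL4 gave 1892, with 940 without _x_at and _s_at probe sets, 852 on the 4 SU-DHL arrays, 877 at 2-fold or more, and 319 (without SU-DHL4 array 2) to 2545 (without SU-DHL6 array 1) leaving out 1 array. Namalwa against the SU-DHL lines gave 2001, with 945 without _x_at and _s_at probe sets, 686 at 2-fold or more, and 187 (without Namalwa array 1) to 2607 (without SU-DHL6 array 1). Where no construction is named, the cause was not tested. For single genes 2738 values kept their side of the threshold, 378 were weaker and 112 stronger; for lists 1327, 87 and 26.

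With the replicate number as a block, 1359 probe sets differed between SU-DHL6 and SU-DHL4 and 1471 between Namalwa and the SU-DHL lines, and CD38 no longer passed in the former. The numbers did not pair the arrays, since same-numbered deviations correlated at -0.444 (Namalwa and SU-DHL4), -0.15 (Namalwa and SU-DHL6) and 0.199 (SU-DHL4 and SU-DHL6). Signal near background limits the dim probe sets, and a fit of those above the median level gave 672 changed probe sets between PCM and B-cell lines.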

Other observations

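No test in this part was chosen only after the result was seen, but the genes were picked from the lists after their values were seen. Some genes had large mean differences between PCM and B-cell lines without passing the test. TNFAIP3, which restrains NF-kB, had a difference of 2.26 (SE 0.43, adjusted p = 0.0650), and REL, an NF-kB subunit, of -2.70 (SE 0.54, adjusted p = 0.0692), over 3 PCM and 3 B-cell lines. ID2, an inhibitor of B-lineage factors, differed by 2.23 (SE 0.50, adjusted p = 0.0911) and the costimulatory gene CD86 by -2.52 (SE 0.50, adjusted p = 0.0693). IL6R, the IL6 receptor gene, differed by 2.53 (SE 0.84, adjusted p = 0.189). The chaperone gene HSP90B1 differed by 2.45 (SE 0.46, adjusted p = 0.0601). Each of these 6 genes passed when each of the 9 arrays was a replicate or line was a random block. Those fits leave the differences unchanged and draw on duplicate arrays, which are not further lines, so passing there adds no support.

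The integrin gene ITGB7, a MAF target, had its highest level in LP1 (11.47, log2), then L363 (10.54), SU-DHL6 (9.55), SU-DHL4 (9.50), U266 (8.48) and Namalwa (7.62). MYC, the oncogene rearranged in Burkitt lymphoma, lay between 10.22 (SU-DHL6) and 11.82 (LP1), with Namalwa at 10.92. CCND3 was highest in Namalwa (11.41) and lowest in L363 (8.76).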
